A study of Drosophila melanogaster with 7 samples.

How the data were processed

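CUT&RUN was performed on unfixed cells with rabbit anti-CLAMP antibody or control rabbit IgG, per the labels' protocols. Cells of both lines were grown at 25 °C, equal numbers of cells were used, libraries were made from 1 ng of DNA with 14 PCR cycles, and sequencing was paired-end with 25 bp reads, per the labels. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2 and MACS2 and the build dm6, without versions or parameters. Whether the IgG libraries served as the control of the peak calling, and whether duplicate reads were removed, is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures. The permutation tests over splits of the libraries therefore measure the spread between these libraries, which may be technical. Fisher's exact tests and the length-matched random lists count regions or genes, and their p-values hold no spread between libraries. The title of the library used as S2 replicate 3 and the name of its deposited list carry different internal sample numbers. The library was taken as its title gives it.

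The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. The lists are in the narrowPeak layout of MACS2, where each row is a summit and several rows can share an interval. The deposited score is the whole-number part of 10 times the −log10 p-value, and was not used. The deposited fold is the ratio of the signal at the summit to the background that the caller estimated, and which library gave that background is not given in the sources used here. The deposited −log10 p-value and −log10 q-value (neg_log10_p) belong to the summit, and the lowest −log10 p-value lay between 2.00 and 2.03 in every list. Fold and p are the authors' values for single peaks, and were used only to filter and rank peaks within a list.

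Rows with the same interval were joined into 1 peak that kept its strongest summit. Peaks on X, 2L, 2R, 3L, 3R and 4 entered the comparisons, and those on Y and the mitochondrial genome were counted apart. Read numbers are not in the peak lists, so the depth per library is unknown and differences in depth cannot be separated from differences in binding. Shares of peaks or regions carry 95% Wilson intervals, which cover counting error only, since reads were amplified by PCR and no molecular identifiers are described.

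Peaks of 2 lists were said to overlap when they shared at least 1 bp. Overlap expected from position alone was estimated from 100 circular shifts of the second list along each arm with a fixed seed. Regions were the merged union of the peaks of the 5 CLAMP libraries, where intervals that only touch stay separate. A library held a region if one of its peaks lay in it. S2-only regions were held by all 3 S2 and no Kc library, Kc-only regions by both Kc and no S2 library, and shared regions by all 5, and regions overlapping a peak of either IgG library were set aside for both lines alike. The strength of a region was the mean percentile of its highest fold within the lists of the libraries that had to hold it.

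Genes came from a RefSeq gene table of the assembly Release 6 plus ISO1 MT, the assembly that dm6 represents, with 17684 genes on the main arms, 13922 of them protein-coding. The table gives the start and end of each gene without strand, transcript starts or exons, and a genome sequence was not used here. The planned shares of peaks at promoters, in introns and at GA repeats were therefore not computed. In place of the promoter share, a gene-end share was taken, with the summit within 500 bp of either end of a gene, and for a gene to hold a region the region had to overlap the gene or the 500 bp to either side. The intergenic share of regions was added beside it. These changes were made after the data had been seen. Gene names follow the table, which gives hry, Flacc and CG4456 for names of the lists that are older synonyms.

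The lists of genes, the comparisons and their tests were fixed before the data were examined. Lines were compared by exact permutation tests over the 10 splits of 5 libraries into 3 and 2, for which the smallest possible p is 0.1. Region classes were compared by Fisher's exact test, two-sided. Each of the 17 gene lists was compared with all other genes for 3 region classes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 51 tests. Lists made only of protein-coding genes were set against protein-coding genes. A second test, added after seeing the data, drew 10000 random lists with genes matched in length, within bins of 200 genes of similar length, and was one-sided. Of the listed genes, 26 of 27 in the ecdysone list and 12 of 13 in the germline list had a single match in the table.

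Named genes were, by a rule fixed at the same time, every member of the dosage compensation and sex determination lists, the genes at the 10 strongest regions of each class, and up to 4 members of each other list by strength. Where the rule asked for the nearest gene start, the nearest gene end was used. Further members of the lists that passed the test, or whose count was 5 or fewer, were named after their values were seen.

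Alternatives were peaks with a q-value at or below 0.0001, equally long lists made of the strongest peaks by p, peaks or regions with other rules on IgG overlap, summit windows of 100 bp to each side in place of intervals, S2 regions in at least 2 of the 3 libraries, gene ends within 200 or 1000 bp, gene ends only for the gene lists, and leaving out each CLAMP library in turn. A block on the replicate number used replicates 1 and 2 of both lines. Leaving out windows of 1 Mb with fewer than 60 genes was added after seeing the data, as was the IgG overlap of regions held by every CLAMP library with shifted IgG peaks and with 1 library left out.

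The procedure was tested on simulated data, lists with 200 S2-only, 200 Kc-only and 500 shared regions placed at known positions among single-library peaks. All were recovered when every library detected every site. When each library detected 90% of its sites, the regions called were 73.5% as many as planted for S2-only, 79.0% for Kc-only and 55.6% for shared. The rule that all libraries must agree thus misses sites that single libraries miss. Called regions were not matched to planted ones, so shared sites called as line-only are counted in. Replicates overlapped far less in the real lists, down to 26.6% of S2 replicate 1 peaks with S2 replicate 3. Errors at such rates were not simulated. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.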

Results

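Binding of CLAMP to chromatin was mapped by CUT&RUN, in which an antibody directs a nuclease to the bound sites and the released DNA is sequenced. CLAMP is a zinc-finger protein that binds GA-rich DNA and takes part in dosage compensation, the doubling of transcription from the single X chromosome of male flies. The cells were S2, a male *Drosophila melanogaster* embryonic line, and Kc, a female embryonic line. The peak lists covered 3 CLAMP libraries from S2, 2 CLAMP libraries from Kc and 1 library with control rabbit IgG from each line. A further Kc CLAMP sample was dropped by the submitters for want of material. Coordinates are those of the dm6 build. Peaks were counted on the main arms X, 2L, 2R, 3L, 3R and 4. The question stated for the series was where CLAMP binding differs between the male and the female line.

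The S2 CLAMP lists held 8904, 8801 and 5535 peaks on the main arms (replicates 1 to 3), and the Kc CLAMP lists held 9832 and 8769. The IgG lists held 1165 peaks in S2 and 8615 in Kc. CLAMP peaks covered 4.91, 4.28 and 2.06 Mb in the S2 libraries and 3.78 and 3.98 Mb in the Kc libraries, against 0.462 Mb in S2 IgG and 3.08 Mb in Kc IgG. The median peak width was 423, 395 and 245 bp in S2 and 292 and 319 bp in Kc. The number of CLAMP peaks did not differ between the lines beyond the spread of the libraries, with 7747 ± 1916 in S2 (SD, n = 3) and 9301 ± 752 in Kc (SD, n = 2), exact two-sided permutation p = 0.6. S2 replicate 3 stood apart within its group: 32.7% of its peaks had a q-value at or below 0.0001, against 75.8% and 76.4% in S2 replicates 1 and 2 and 53.7% and 67.1% in the Kc libraries. The numbers of reads behind the lists were not given in the sources used here, so the depth is unknown. Fold enrichments are the authors' own values for single peaks and serve only to rank peaks within a list.

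The genes of the dosage compensation machinery itself were bound unevenly. The gene for roX1, a noncoding RNA of the male dosage compensation complex, carried peaks in all 3 S2 CLAMP libraries and in neither Kc library. The gene for roX2, the partner RNA, carried peaks in all 5 CLAMP libraries and in no IgG library. The gene for CLAMP (Clamp, 2L 22165720 to 22169143) also carried peaks in all 5, but that of S2 replicate 3 (2L 22167657 to 22167880, fold 1.86) lay outside the region of the other 4 (2L 22168375 to 22169899) and was lost at a q-value of 0.0001 or less. For mof, the histone acetyltransferase gene of the complex, peaks were called in both Kc libraries and in no S2 library.

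At roX1 (X 3857230 to 3862697) a central peak lay inside the gene, with its summit at X 3861324 in S2 replicates 1 and 2, where it was the strongest at the gene, and at X 3861306 in replicate 3. Its fold enrichment was 6.10, 11.1 and 2.20 in S2 replicates 1 to 3. By p-value it ranked 80 among the 8904 peaks of replicate 1, 39 among the 8801 of replicate 2 and 518 among the 5535 of replicate 3. By fold, its percentile within the list was lower in replicate 3, with 90.7, 97.1 and 58.1 in replicates 1 to 3. A further peak at X 3857829 to 3858170 was held by S2 replicates 1 and 3 and was the strongest at the gene in replicate 3 (fold 2.71, rank 282 by p-value). Another at X 3862494 to 3862773 was held by S2 replicates 1 and 2. The S2 IgG library also had a peak inside the central region, at X 3860908 to 3861190. That peak had a fold of 2.45, rank 923 of 1165 by p-value and a percentile of 26.9 by fold. By the rule on IgG, roX1 was therefore set aside from the S2-only regions. At roX2 (X 11579065 to 11580432) a region at X 11578922 to 11580805 was shared by all 5 CLAMP libraries. Its highest fold was 8.40, 11.8 and 4.57 in the S2 libraries and 2.67 and 4.83 in the Kc libraries. The mof peaks of the Kc libraries did not overlap one another: they lay at X 5873094 to 5873365 and X 5874597 to 5874834 in replicate 1 and at X 5873895 to 5874094 in replicate 2. Among the other listed genes, JIL-1 held peaks in 4 CLAMP libraries, Unr in 2, and msl-1 and mle in S2 replicate 1 alone. The region of the mle peak was held by 2 CLAMP libraries, but only the S2 replicate 1 peak reached within 500 bp of the gene. No peak was called at msl-2 or msl-3. With peaks at a q-value of 0.0001 or less, mof held a peak in 1 of the 2 Kc libraries.

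**Figure D1:**
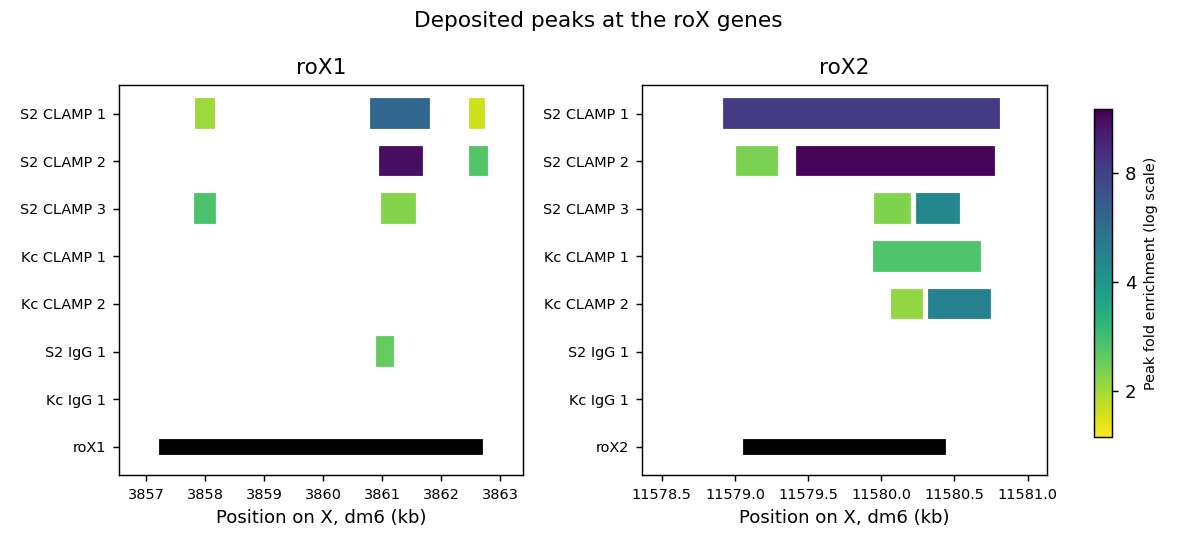
Peaks at roX1 and roX2 on X (horizontal axis, dm6 position in kb) in the 7 libraries (rows), coloured by fold enrichment on a log scale, with the annotated gene as a black bar. The roX1 gene held peaks in 3 S2 CLAMP libraries and S2 IgG and in neither Kc CLAMP library, while roX2 held peaks in all 5 CLAMP libraries.

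Of 22 sex determination genes, 18 held a peak in at least 1 CLAMP library and 3, namely emc, fru and Mettl3, held one in all 5. The Mettl3 peak of S2 replicate 3 (3R 24034017 to 24034216, fold 1.77) lay apart from the region of the other 4 (3R 24031061 to 24032070) and was lost at a q-value of 0.0001 or less. Sxl, the switch gene of female development, held a Kc-only region at X 7095171 to 7095660, inside the gene (X 7074550 to 7098053), with a fold of 2.41 and 2.94 in Kc replicates 1 and 2. A second Sxl region at X 7096884 to 7098045, which reached the upper end of the gene, was held by both Kc libraries and by S2 replicates 1 and 2. The gene fru, which directs male courtship behaviour, held 1 Kc-only region at 3R 18473453 to 18473733 and 2 shared regions. The Kc-only region had folds of 2.69 and 1.93 in Kc replicates 1 and 2. Its peak in Kc replicate 2 (−log10 q 3.23) was lost at a q-value of 0.0001 or less. Beside it lay a region at 3R 18473781 to 18474940 held by both Kc libraries and by S2 replicates 1 and 2. The region at emc, an inhibitor of helix-loop-helix factors, was shared at 3L 748447 to 749636, with folds of 13.9, 5.68 and 3.08 in S2 and 4.32 and 10.9 in Kc. Peaks were called at tra2, dsx and gro in 4 CLAMP libraries, at fl(2)d and Flacc in 3, at da, nito, ix and tra in 2, and at her, vir, dmrt99B, sisA and upd1 in 1. The region of the her peak was held by 3 CLAMP libraries, but only the S2 replicate 1 peak reached within 500 bp of the gene. No CLAMP peak was called at dpn, sc, snf or run. Kc IgG also had a peak at dsx, gro and dmrt99B, and S2 IgG at fru, snf and run.

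The CLAMP libraries shared many peaks across the lines as well as within them. The base-pair Jaccard index, the overlap of 2 lists divided by their union, was 0.491 between S2 replicates 1 and 2 and 0.364 between the Kc replicates. S2 replicate 3 reached only 0.186 and 0.218 with S2 replicates 1 and 2. Between lines the index ran from 0.151 for S2 replicate 3 with Kc replicate 1 to 0.365 for S2 replicate 1 with Kc replicate 2. The mean was 0.315 within lines and 0.263 between lines, a difference of 0.0518. In an exact one-sided permutation test 2 of the 10 splits of the 5 libraries gave a difference as large (p = 0.2). The smallest p this design allows is 0.1. Without S2 replicate 3 the difference was 0.111, and without Kc replicate 1 it was 0.0141.

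Part of the CLAMP peaks also appeared with control IgG. In Kc, 22.6% of the peaks of either CLAMP library overlapped a Kc IgG peak by at least 1 bp, against 4.58% and 4.90% when the IgG peaks were shifted along the arms. Of the S2 CLAMP peaks 5.54%, 5.70% and 8.20% overlapped an S2 IgG peak, against 0.807%, 0.755% and 0.620% with shifted IgG peaks. The observed share was 6.86, 7.56 and 13.2 times the shifted one in S2, and 4.94 and 4.62 times in Kc. Since the S2 IgG list held 1165 peaks and the Kc IgG list 8615, the plain shares are not comparable between the lines. A Kc IgG peak was overlapped by 13.7%, 19.7% and 26.1% of the S2 CLAMP peaks, against 5.40%, 5.08% and 4.43% with shifted peaks. Of the Kc IgG peaks, 23.6% and 22.6% overlapped peaks of Kc CLAMP replicates 1 and 2, whereas 54.3% of the peaks of Kc CLAMP replicate 1 overlapped those of replicate 2. Of the 1250 merged regions held by all 5 CLAMP libraries, which had a median width of 1213 bp and so were wider than single peaks, 54.2% overlapped a Kc IgG peak and 22% an S2 IgG peak, against 9.27% and 1.38% with shifted IgG peaks. Without S2 replicate 3 these shares were 27.1% and 10.4% of 2817 regions.

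The X chromosome held 19.8%, 20.02% and 12.1% of the CLAMP peaks in S2 replicates 1 to 3 and 24.3% and 21.2% in the Kc replicates. X makes up 17.6% of the length of the main arms. Its copy number in the 2 lines was not measured, so these shares were not corrected for it. The mean share was 17.3% ± 4.52 in S2 (SD, n = 3) and 22.7% ± 2.19 in Kc (SD, n = 2), and both Kc libraries lay above all 3 S2 libraries. The difference of -5.43 points did not pass the exact two-sided permutation test on group means (p = 0.3, smallest possible p 0.1). Without S2 replicate 3 the difference was -2.82 points. Chromosome arm 2L held a larger share in S2 than in Kc, 19.1% ± 2.45 against 14.1% ± 0.597 (SD, n = 3 and 2), and 3R a smaller one, 21.7% ± 0.197 against 23.4% ± 0.153. For both arms no other split of the libraries gave a mean difference as large (exact two-sided permutation p = 0.1, the smallest possible), and the adjusted p was 0.6 by the Benjamini-Hochberg method over the 12 measures tested between the lines. In the IgG libraries X held 33.6% of the peaks in S2 and 16.2% in Kc.

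**Figure D2:**
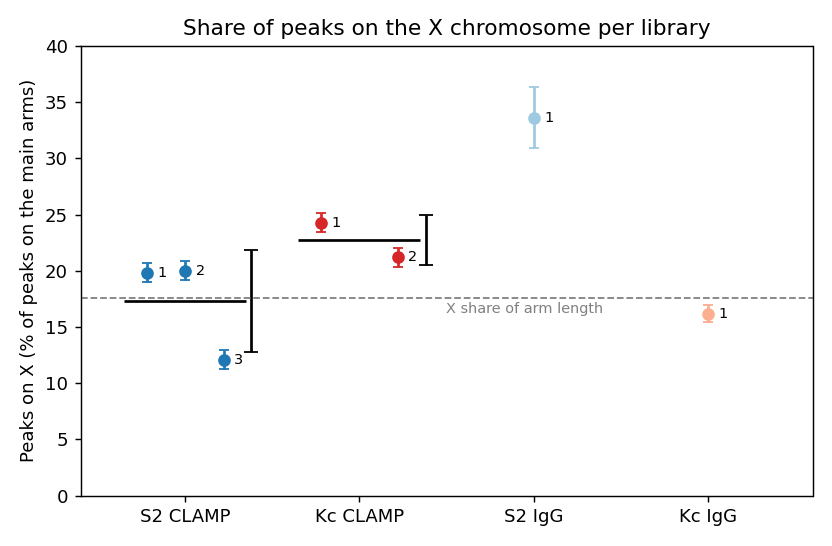
Share of peaks on X (vertical axis, percent of the peaks on the main arms) in the 7 libraries, grouped by line and antibody, with replicate numbers, 95% Wilson intervals, the mean ± SD of the CLAMP groups in black and the X share of arm length as a dashed line. S2 replicate 3 lies at 12.1%, below the 19.8% to 24.3% of the other CLAMP libraries, and S2 IgG at 33.6%.

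CLAMP summits lay near gene ends more often than IgG summits in these lists, a difference not tested with 1 IgG library per line. Within 500 bp of either end of an annotated gene lay 38.5%, 24.5% and 18.3% of the summits in S2 replicates 1 to 3 and 24.5% and 29.9% in the Kc replicates, against 13.4% in S2 IgG and 11.9% in Kc IgG. The gene interior held 46.8% ± 2.60 in S2 and 51.3% ± 4.81 in Kc (SD, n = 3 and 2), and intergenic DNA 26.1% ± 7.75 and 21.5% ± 1.01. The gene-end share was 27.1% ± 10.3 in S2 and 27.2% ± 3.80 in Kc, a difference far inside the spread of the libraries (exact two-sided permutation p = 1). Its sign changed with several of the settings tried. The gene table used gives gene boundaries without strand, transcript starts or exons, so starts and 3′ ends were not told apart.

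Merging the peaks of the 5 CLAMP libraries gave 19039 regions, of which 10997 (57.8%) were held by a single library. After regions overlapping an IgG peak were set aside, 272 regions were held by all 3 S2 libraries and no Kc library (S2-only), 424 by both Kc libraries and no S2 library (Kc-only), and 556 by all 5 (shared). The leading S2-only regions lay near Spf45 and Scp1 and at Tet, the leading Kc-only regions at tio and nearest to lncRNA:CR46482 and IntS3, and the leading shared regions at lncRNA:CR46085 and FBXO11 and near disco. The cell lines were not the grouping with the most side-specific regions. Over the 10 splits of the libraries into 3 and 2, the cell lines gave 696 such regions, while the split of S2 replicates 1 and 2 from the other 3 libraries gave 996.

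The counts moved with single libraries, in part because a smaller number of lists has to agree. S2-only regions numbered 1269 without S2 replicate 3 and 434 without S2 replicate 1. Kc-only regions numbered 735 without S2 replicate 1, 2279 without Kc replicate 1 and 3550 without Kc replicate 2. Shared regions numbered 2025 without S2 replicate 3. No p below 0.1 is possible for a single region.

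**Figure D3:**
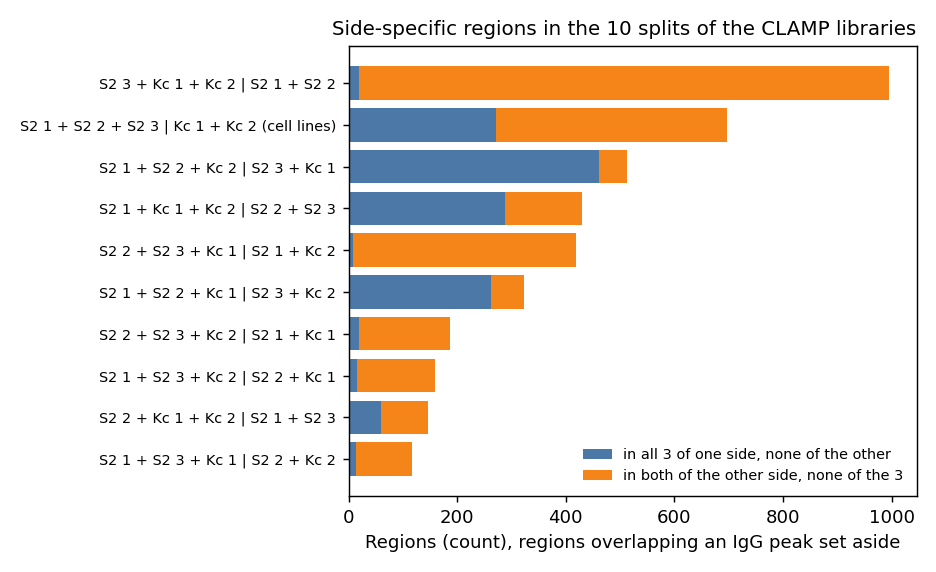
Number of regions (horizontal axis) held by every library on one side of a split and by none on the other, for the 10 splits of the 5 CLAMP libraries into 3 and 2, in blue for the side of 3 and in orange for the side of 2. The split by cell line gives 272 and 424, and the split of S2 replicates 1 and 2 from the rest gives 20 and 976.

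The strongest S2-only region lay at 2L 23065787 to 23066144, 953 bp outside Spf45, a splicing factor gene, with folds of 13.6, 16.5 and 6.48 in the S2 libraries. The next lay at 2R 2977484 to 2977909, 9660 bp from Scp1, with folds of 12.6, 14.3 and 7.40, and at 3L 2866790 to 2867977 inside Tet, the gene of a TET family dioxygenase, with folds of 11.04, 14.6 and 3.97. Regions inside CG42699 (X 5788126 to 5789452), CG42238 (2L 21041831 to 21042741) and Npl4 (3R 25624190 to 25624839) and at the end of CG5541 (X 15051355 to 15052447) followed. The remaining S2-only regions of the first 10 lay outside genes, nearest to lncRNA:CR40469, robo3, an axon guidance receptor gene, and lncRNA:CR42646. The regions nearest Spf45, Scp1 and lncRNA:CR42646 lay in windows of 1 Mb with fewer than 60 genes.

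The strongest Kc-only region lay at 2L 22024235 to 22024895 inside tio, a zinc-finger gene, with folds of 5.19 and 9.86 in the Kc libraries. Regions at 3L 27911492 to 27912142 and 2R 4270536 to 4272773 were intergenic, 30427 bp from lncRNA:CR46482 and 28080 bp from IntS3. Those at Ugt302C1 (3R 11156695 to 11157220), meso18E (X 19712286 to 19713628) and betaTub97EF (3R 27987716 to 27988432) lay at gene ends. Regions inside cpo, an RNA-binding protein gene (3R 17948942 to 17949980), and CG44838 (3L 9465406 to 9466226) and near lncRNA:CR40469 and lovit completed the first 10. The S2-only and Kc-only regions nearest lncRNA:CR40469 were separate, at X 95128 to 95673 and X 96648 to 97605. The regions at tio and nearest lncRNA:CR46482, IntS3 and lovit lay in windows of 1 Mb with fewer than 60 genes.

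The strongest shared region lay at 3R 27244635 to 27246315 over lncRNA:CR46085, with folds of 12.2, 16.03 and 5.29 in S2 and 4.09 and 13.1 in Kc. It was followed by regions at FBXO11, an F-box gene (3R 9808620 to 9809402), 777 bp outside disco, a zinc-finger gene (X 16216549 to 16218109), and at Dek (2R 16855969 to 16857503) and Hmt4-20, a histone H4 methyltransferase gene (X 654193 to 656037). The homeobox genes en (2R 11527745 to 11528674) and hth (3R 10614214 to 10614897), the SR protein kinase gene SRPK (2R 15380428 to 15381569), the repressor gene ttk (3R 31713017 to 31714129) and the GTPase gene Rab35 (X 20158828 to 20160097) held the others. With regions built from windows around summits, 7 of these 10 shared regions (not those of disco, Hmt4-20 and Rab35), 9 of the 10 S2-only regions (not that of CG42699) and 10 of the 10 Kc-only regions were still in their class.

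The X chromosome held a larger part of the Kc-only than of the S2-only regions. On X lay 131 of the 424 Kc-only regions (30.9%, 95% Wilson interval 26.7 to 35.4), 47 of the 272 S2-only regions (17.3%, 13.3 to 22.2) and 62 of the 556 shared regions (11.2%, 8.80 to 14.0). The odds ratio of X for S2-only against Kc-only regions was 0.468 (95% interval 0.314 to 0.689, Fisher's exact test, two-sided, p = 5.76e-05, 1.53e-04 after Benjamini-Hochberg adjustment over 12 tests). Regions of the same libraries are not independent replicates, so the test and the intervals describe these libraries and cover counting error only. The difference of -13.6 points became 2.46 points (Fisher's exact p = 0.699) with peaks at q of 0.0001 or less, and -5.91 points (p = 0.178) with equally long lists. Without Kc replicate 1 it was -3.70 points (Fisher's exact p = 0.139), without S2 replicate 3 it was -8.52 points (p = 3.4e-04), and without the latter the shared regions lay on X in 22.7% of cases. With no region set aside for IgG, 20.2% of the 1250 shared regions lay on X.

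S2-only regions lay in intergenic DNA more often than Kc-only regions, 89 of 272 (32.7%, 27.4 to 38.5) against 58 of 424 (13.7%, 10.7 to 17.3), an odds ratio of 3.06 (2.07 to 4.55, Fisher's exact test, two-sided, p = 4.02e-09, adjusted 1.61e-08). They lay near gene ends less often, 20.2% against 28.5% (Fisher's exact test, two-sided, p = 0.0157, adjusted 0.0242). Of the shared regions 14.2% were intergenic and 33.6% at gene ends. Without S2 replicate 3 the intergenic shares of S2-only and Kc-only regions were 18.5% and 15.1% (Fisher's exact p = 0.112). The gene-end difference of -8.32 points became 2.58 points without S2 replicate 3, 2.59 without Kc replicate 2 and -2.23 without S2 replicate 2. It grew to -17.6 points without S2 replicate 1. With most other settings it fell short of the threshold. The shares lay further apart with summit windows (19.7% of S2-only against 32.0% of Kc-only) and with only the IgG of the line itself (19.1% against 28.6%).

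**Figure D4:**
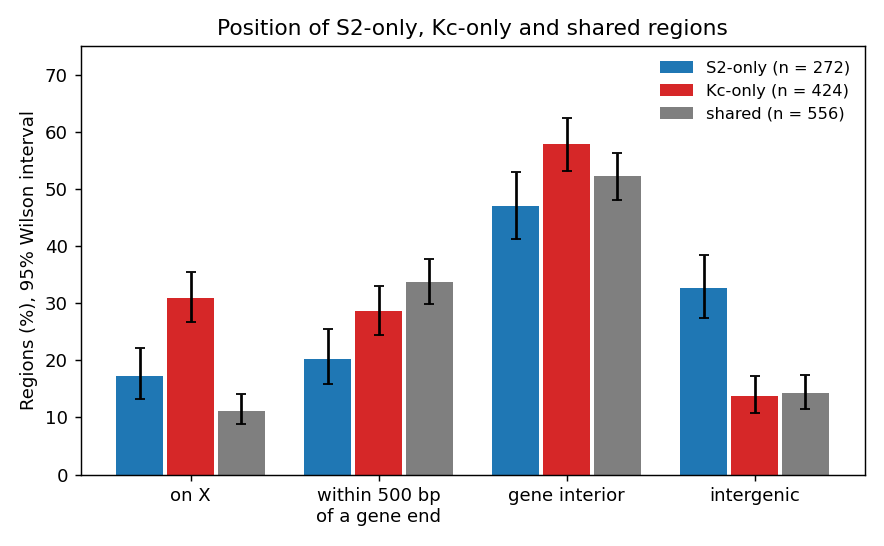
Share of S2-only, Kc-only and shared regions (vertical axis, percent, with 95% Wilson intervals) on X and in 3 positions relative to genes. Kc-only regions lie on X in 30.9% of cases against 17.3% of S2-only regions, and S2-only regions are intergenic in 32.7% against 13.7%.

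Genes of chromatin regulators that act at GA-rich sites and Polycomb sites held shared regions more often than other genes. Of 22 such genes, 8 (36.4%) held a shared region against 3.81% of the other protein-coding genes. They were Trl, the gene of GAGA factor, psq and lola, which encode BTB-domain factors, grh, and the Polycomb genes Psc, Su(z)2, ph-d and ph-p. The regions at Su(z)2 (2R 12996182 to 12997651), ph-d (X 2122584 to 2124909), Psc (2R 12979915 to 12981371) and ph-p (X 2136750 to 2138787) were the strongest, with mean percentiles in their lists of 92.8, 91.7, 89.7 and 82.5. The odds ratio was 14.4 (95% interval 5.22 to 37.1, Fisher's exact test, two-sided, adjusted p = 4.7e-05 over 51 tests, from 17 lists and 3 region classes). Random lists matched for gene length held 1.94 such genes on average (permutation test, one-sided, adjusted p = 0.0102). Psc and Su(z)2 lie close together on 2R, and ph-d and ph-p on X. Both tests count each gene singly, so they do not allow for such neighbours.

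Ecdysone response genes, which answer the moulting hormone, held both Kc-only and shared regions. Of 26 matched genes, 7 (26.9%) held a Kc-only region: Eip78C with 3 regions, Eip75B with 2, and Eip63E, ftz-f1, Eip93F, br and Hr4 with 1 each. Shared regions were found at 7, namely Eip74EF with 9 regions, Eip63E and ftz-f1 with 3 each, Hr39 and Eip75B with 2 each, and EcR and br with 1 each. S2-only regions lay at br with 1 and Hr4 with 3. The strongest of these regions were at Hr39 (2L 21250402 to 21251259, mean percentile 96.0) and Eip74EF (3L 17577347 to 17578430, 95.9). Against other protein-coding genes the Fisher's exact test gave adjusted p = 1.45e-04 for Kc-only and 7.21e-04 for shared regions (two-sided). The listed genes are long, with a median of 20597 bp against 2163 bp, and against random lists matched for length the adjusted permutation p was 0.0530 and 0.135. With gene ends alone in place of whole genes 1 gene held a Kc-only and 2 a shared region, and neither test passed. Without Kc replicate 2 the Kc-only count was 15, and without S2 replicate 3 the shared count was 15.

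Heat shock genes held Kc-only and shared regions and, with all 5 libraries, no S2-only region. Shared regions lay at Hsp70Ba, Hsp68, lncRNA:Hsromega, Hsp70Bb and Hsp70Bbb, 5 of 21 genes (23.8%, adjusted Fisher's exact p = 0.00931, length-matched adjusted permutation p = 0.0102). Kc-only regions lay at Hsc70-3 (X 11806122 to 11806473), Hsp22, Hsp67Bc and CG4456, 4 of 21 genes (adjusted p = 0.0130 by Fisher's exact test and 0.0127 by the length-matched permutation). The last 3 of these genes share 1 region at 3L 9372595 to 9373100, and Hsp70Bb and Hsp70Bbb share 1 at 3R 12505288 to 12506110. Both tests count each gene, so these single regions entered more than once and the p-values do not allow for it. The Hsp70 genes are near-identical copies, so the peaks at each copy are uncertain. No IgG peak was called at a gene of this list. The Kc-only count was 7 without S2 replicate 1, 8 without Kc replicate 2 and 5 without Kc replicate 1, where the test no longer passed (adjusted Fisher's exact p = 0.239), and the shared count was 14 without S2 replicate 3 and 8 without Kc replicate 1.

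Splicing and RNA-binding genes held shared regions at 6 of 33, RnpS1, ps, mbl, pAbp, Rox8 and heph (adjusted Fisher's exact p = 0.0130, length-matched adjusted permutation p = 0.354), and at 13 without S2 replicate 3. Kc-only regions lay at 1 of them, but at 7 without S2 replicate 1, where the test passed (adjusted Fisher's exact p = 0.0121). Without the windows of 1 Mb with fewer than 60 genes, 5 of 33 held a shared region and the test did not pass (adjusted Fisher's exact p = 0.0561). Hemocyte genes, which mark the blood cell type that both lines resemble in expression, held Kc-only regions at 4 of 26, vkg, ush, Hml and Pvr (adjusted Fisher's exact p = 0.0420, length-matched adjusted permutation p = 0.285), with mean percentiles of 69.3, 55.1, 33.8 and 30.7. This test did not pass without S2 replicate 1 (adjusted Fisher's exact p = 0.0598) or Kc replicate 1 (0.143, at 7 genes) or with no region set aside for IgG (0.0630), and the count was 10 without Kc replicate 2. With gene ends alone neither the splicing nor the hemocyte list passed. Of the 111 histone cluster genes, all held a CLAMP peak in at least 1 library and 49 in all 5. A Kc IgG peak also lay at 81 of them, and shared regions were held by 44 with no region set aside for IgG (adjusted Fisher's exact p = 1.08e-26) and by 9 under the IgG rule (adjusted Fisher's exact p = 0.157, length-matched adjusted permutation p = 0.0102). Under that rule the adjusted Fisher's exact p was 0.0314 with gene ends alone, 0.0176 without S2 replicate 1 (11 genes) and 0.0127 without Kc replicate 2 (12 genes), and 19 genes held a shared region without S2 replicate 3 (0.314). Kc-only regions lay at 2 of the 111 genes with all 5 libraries, at 21 without S2 replicate 2 (18.9% against 3.04% of other genes, adjusted Fisher's exact p = 1.74e-09) and at 8 without Kc replicate 2, a lower share than in other genes (7.21% against 16.7%, adjusted Fisher's exact p = 0.0267). The histone genes are repeated in near-identical units, so their reads cannot be assigned to single copies with certainty.

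The other lists did not pass the adjusted test with all 5 libraries. Shared, S2-only and Kc-only regions were held by 2, 0 and 2 of 22 sex determination genes, 1, 0 and 0 of 10 dosage compensation genes, and 2, 0 and 0 of 14 insulator genes, with the shared ones at mod(mdg4) and pzg. The same numbers were 1, 1 and 1 of 25 Hox and segmentation genes (en, gt and hry), 1, 2 and 1 of 85 ribosomal protein genes (RpS9, RpLP1 and RpL23, RpL12), 0, 0 and 3 of 20 neuronal and glial genes (brp, Vmat and elav) and 0, 0 and 0 of 12 germline genes. They were 3, 0 and 0 of 17 muscle genes (Mef2, Tm1 and sls), 2, 0 and 3 of 23 immune genes, with shared regions at imd and Dif and Kc-only regions at PGRP-LE, Dif and cact, 3, 0 and 1 of 20 cell cycle genes (E2f1, stg and CycD, and Dp), and 3, 0 and 0 of 18 housekeeping genes (sesB, Act5C and Pgk). No list passed for S2-only regions with all 5 libraries. In all, 7 of the 51 tests passed at an adjusted p below 0.05 with a higher share in the list. Without S2 replicate 3 there were 12, the further ones for shared regions at 8 of 18 housekeeping genes and for S2-only regions at 6 of 25 Hox and segmentation, 9 of 33 splicing, 6 of 26 ecdysone and 8 of 26 hemocyte genes. Without Kc replicate 2, S2-only regions at 3 of 21 heat shock genes (adjusted Fisher's exact p = 0.0292) and 4 of 26 ecdysone genes (0.0127) passed, and Kc-only regions were rarer at ribosomal protein genes (4 of 85, 4.71% against 16.7% of other genes, 0.0122). Without Kc replicate 1, Kc-only regions at 7 of 20 neuronal and glial genes passed (adjusted Fisher's exact p = 0.0410). Whether a list differed between S2-only and Kc-only regions was not tested.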

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

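The test on the strongest regions common to the Kc libraries and that on the stronger line-only regions were fixed before their results were seen. Leaving out single libraries was planned before the data were seen, but its use to weigh S2 replicate 3 here, like the other tests in this part, was chosen after the pattern was seen. The X share of CLAMP peaks lay below that of IgG in S2 and above it in Kc. The mean difference between CLAMP and IgG was -16.3 points in the 3 S2 libraries and 6.57 points in the 2 Kc libraries, and every S2 library lay below and every Kc library above the IgG library of its line. The lines also moved apart on 3R, with 4.68 points in S2 and -6.04 points in Kc, and on chromosome 4, with -1.83 and 0.276 points. With 1 IgG library per line these differences between the lines were not tested.

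S2 CLAMP replicate 3 had fewer peaks than the other S2 libraries and an X share 7.83 points below their mean. Kc material under a wrong label is argued against by the overlap of its peaks, which was 10.6 points higher with the other S2 lists (45.2% and 48.1%) than with the Kc lists (34.9% and 37.2%). At peaks with q at or below 0.0001 the gap in X share was 1.77 points, but that threshold keeps 1811 peaks of this list and 6751 and 6726 of the others. Among the 1811 strongest peaks of each list the gap was 4.94 points by p-value and 9.53 by fold, so whether a longer tail of weak peaks makes the gap stays open. Lower depth or weaker enrichment was not tested. The list of replicate 3 shared more with IgG, with a Jaccard index of 0.106 with S2 IgG and 0.145 with Kc IgG. For S2 replicates 1 and 2 the index was 0.0456 and 0.0507 with S2 IgG, and 0.0769 and 0.111 with Kc IgG. Its gene-end share of 18.3% was the lowest of the CLAMP lists, against 13.4% in S2 IgG and 11.9% in Kc IgG. With the other S2 CLAMP lists its index was higher, 0.186 and 0.218. The differing sample numbers of its title and list were not resolved.

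The Kc IgG list held 8615 peaks, nearly as many as the Kc CLAMP lists. A CLAMP library under a wrong label is argued against by the overlap of at most 23.6% of its peaks with a Kc CLAMP list, where the replicates of Kc CLAMP overlap in 54.3% and 56.1%. Carry-over of CLAMP-bound DNA would put IgG peaks at the strongest CLAMP sites first, but among regions common to both Kc CLAMP libraries an IgG peak lay at the summit in 29.7% of the strongest 421 (95% Wilson interval 25.5 to 34.2) and in 49.4% of the weakest 421. Over all 4201 such regions the share was 27.7%, so IgG peaks did not become steadily rarer with strength, and a smaller carry-over is not excluded. Whether this IgG library was the control of the peak calling is not known. If it was, CLAMP folds would be lowered and peaks lost where IgG has signal. The overlap and the ranking by fold would then be shaped by the calling itself, and neither comparison would argue against its explanation. Over 114 autosomal windows of 1 Mb, Kc IgG peaks outside CLAMP regions followed peaks found in one Kc library alone more closely (Spearman's rho 0.309 and 0.525) than those of the S2 libraries (-0.225 to 0.204; windows are not independent), so a background that follows the Kc genome, in copy number or open chromatin, may contribute.

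Kc-only regions lay on X more often than S2-only regions. The low X share of S2 replicate 3 is argued against as the whole cause, since without that library the difference was -8.52 points (Fisher's exact p = 3.4e-04) against -13.6 with it. Weak peaks near the threshold of the lists may make most of the difference: among line-only regions with a mean percentile of at least 75 it was 3.57 points, with 17 of 56 S2-only and 15 of 56 Kc-only regions on X. The sex of the donors cannot be told apart from any other difference between the lines, since each sex is represented by 1 line. Nor can CLAMP binding on X be told apart from the copy number of X in each line, which was not measured.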

How the results depend on the processing

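The gene-end shares, the intergenic share, the lists matched for gene length, the gene-poor windows and the gene lists with a library left out were tests chosen after the data were seen. Of 118 alternatives to the results of the comparisons, 79 kept direction and side of the threshold, or moved by less than 1.5 times for a count, while 9 no longer passed, 20 moved and 10 reversed. The exact permutation tests cannot give a p below 0.1. For the similarity and the shares of peaks the side of the threshold of 0.05 was therefore fixed, and only the direction could change. Of 456 alternatives for single genes and regions named, 427 left the value unchanged or within its limits, 29 moved it and 0 reversed it. By the rules used none of these values could reverse, so the 0 was fixed in advance. Leaving out a library, or loosening the rules on IgG or on the number of S2 libraries, only widens the classes. The named regions could hardly leave their class in those settings. Except where said otherwise, the cause of a change was not tested. The similarity within lines stayed above that between lines in every alternative (0.0141 to 0.111 with 1 library left out), and the X share of peaks stayed lower in S2 (-6.98 to -2.82 points), but neither passed its exact permutation test.

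With peaks at q of 0.0001 or less there were 123 S2-only, 200 Kc-only and 233 shared regions, since fewer peaks entered, and with equally long lists 235 Kc-only regions. With no region set aside for IgG there were 767 Kc-only and 1250 shared regions, and with S2 regions in at least 2 of the 3 libraries 1476 S2-only and 2035 shared, both rules admitting more by construction. Summit windows gave 363 shared regions. With 1 library left out the counts ran from 325 to 1269 for S2-only, 443 to 3550 for Kc-only and 567 to 2025 for shared regions. The share of CLAMP peaks overlapping the IgG peaks of their line was 3.56% in S2 and 18.7% in Kc when at least 0.5 of the length of the peak had to overlap, against 6.48% and 22.6%, and 5.62% to 6.95% in S2 with 1 library left out.

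The difference in X share between S2-only and Kc-only regions reversed to 2.46 points with peaks at q of 0.0001 or less, no longer passed with equally long lists (-5.91 points), and ran from -14.7 to -3.70 points with 1 library left out. The difference in gene-end share of regions no longer passed with gene ends within 200 bp (-1.54), without gene-poor windows (-1.40), with no region set aside for IgG (-2.24), with peaks at q of 0.0001 or less (-4.42) and with equally long lists (-3.42). It reversed with S2 regions in at least 2 of the 3 libraries (2.63) and ran from -17.6 to 2.59 with 1 library left out. The difference in intergenic share ran from 3.39 (without S2 replicate 3, not passing) to 26.6 with 1 library left out and passed in the other alternatives run, though with 8.84 points without gene-poor windows, 7.26 with S2 regions in at least 2 of the 3 libraries and 11.4 with no region set aside for IgG, against 19.04. The gene-end share of peaks, -0.0734 points apart with all libraries, was 2.26 within 200 bp, 0.268 with equally long lists and -5.75 to 4.32 with 1 library left out. Of the gene lists, 4 passed with gene ends only and 4 against lists matched for length, in place of 7. Both times 3 of the 7 passed again (GA-binding and Polycomb factors for shared regions, heat shock for Kc-only and shared) and 1 was new (histone cluster, shared), and 6 to 12 passed with 1 library left out. With gene ends only and lists matched for length together, heat shock and histone cluster passed for shared regions (adjusted permutation p = 0.0102 for each). GA-binding and Polycomb factors for shared regions (adjusted permutation p = 0.0646) and heat shock for Kc-only regions (0.0841) did not.

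Only 2 replicate numbers are common to the lines, and nothing in the labels ties samples of the same number, so the samples were taken to share only a number. In large windows the libraries of the same number did deviate together. Over 138 windows of 1 Mb, the difference between replicates 1 and 2 in S2 followed that in Kc (Spearman's rho 0.350, windows are not independent). Counting peaks found in one library alone, over 114 autosomal windows, rho across the lines was 0.399 and 0.373 for the same number and 0.108 and -0.0650 for different numbers. The base-pair Jaccard index across the lines did not separate the same number (0.280 and 0.326) from different numbers (0.365 and 0.295). The check in windows was chosen after the data were seen, and with 2 pairs it does not settle a shared batch. With the replicate number as a block (replicate block, replicates 1 and 2) the difference was -2.82 points for the X share of peaks. For the gene-end share it was 4.32 points, reversed in sign from -0.0734. These values equal those without S2 replicate 3 by construction. With 2 pairs the test of the block could not pass, so it bears on no call. The planned shares of promoters, introns and GA repeats, with their alternatives, were not run, since strand, exons and sequence were not used here. With unknown depth, a site missing from a list may lie below the threshold of that library: S2 replicate 3, with 5535 peaks, limits every S2-only and shared count, which rose to 1269 and 2025 without it.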

Other observations

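The tests in this part were chosen after the values were seen. Several genes outside the fixed lists held 3 or more regions of one line. The ETS factor gene pnt held 4 Kc-only regions and 1 S2-only region, and 3 Kc-only and no S2-only regions were found at each of mam, the Notch coactivator gene, kirre, an immunoglobulin-family adhesion gene, AMPdeam, Ac13E, CG4301, NK7.1, bmm, a lipase gene, and bol. Among the S2-only regions CG17684 held 5 and CG17839 held 4, and kibra, a Hippo pathway gene, CG41520, CG42238 and Rnf11 held 3 each, with no Kc-only region. Myo81F, which spans 3R 567076 to 2532932, held 5 S2-only, 3 Kc-only and 6 shared regions, and the piRNA locus lncRNA:flam held 3, 2 and 3. These genes were picked by their counts, and long genes can hold more regions.

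S2-only regions were common in gene-poor DNA. Windows of 1 Mb with fewer than 60 genes, 23 of the 138 windows, held 86 of the 272 S2-only regions (31.6%, 95% Wilson interval 26.4 to 37.4), 33 of the 424 Kc-only regions (7.78%, 5.60 to 10.7) and 39 of the 556 shared regions (7.01%). The odds ratio of S2-only against Kc-only was 5.48 (Fisher's exact test, two-sided, p = 1.01e-15). Without S2 replicate 3 the shares were 12.7% of 1269 S2-only and 8.35% of 443 Kc-only regions, and without Kc replicate 1 they were 31.7% of 325 and 17.9% of 2279. Of the peaks of single lists, 13.2%, 23.2% and 25.4% of the S2 CLAMP, 13.8% and 18.8% of the Kc CLAMP, 31.0% of the S2 IgG and 27.2% of the Kc IgG peaks lay in these windows.

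In S2 the X share was higher among strong than among weak peaks of the same list. With each list parted by fold into 4 parts of equal size, the share in the weakest and the strongest part went from 15.3% to 24.2% in S2 replicate 1, from 14.4% to 26.7% in replicate 2 and from 11.5% to 19.2% in replicate 3. The same shares were 23.8% and 25.5% in Kc replicate 1 and 19.97% and 26.2% in Kc replicate 2. In S2 IgG they were 21.2% and 41.2%, and in Kc IgG 13.5% and 20.9%. The rise was not steady in S2 replicate 3, where parts 2 and 3, counted from the weakest, held 7.66% and 9.98%.

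Regions held by S2 replicates 1 and 2 and both Kc libraries but not by S2 replicate 3 numbered 1455 after the IgG rule, and 27.1% of them lay on X. Under that rule the regions held by all 5 libraries lay on X in 11.2% of cases, and those held by S2 replicate 3 alone in 4.80% of 2145. With no region set aside for IgG, 20.2% of the 1250 regions held by all 5 lay on X.

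The S2 IgG list differed in kind from the others. Of its 1165 peaks, 413 (35.5%) had a fold above 20, against 13 to 41 peaks in each of the other lists. These 413 peaks had a median width of 378 bp, with 5th and 95th percentiles of 374 and 403 bp, and a median −log10 p-value of 1398. On X lay 40.4% of them and 29.8% of the remaining S2 IgG peaks, and 4.12% to 11.9% of them overlapped peaks of the single CLAMP lists.

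Every list also held peaks on Y, with 169, 206 and 160 in S2 CLAMP, 150 and 156 in Kc CLAMP, 62 in S2 IgG and 206 in Kc IgG. As a share of all peaks these were below the IgG library of the same line in S2 replicates 1 to 3 (1.86%, 2.28% and 2.80% against 5%) and in the Kc replicates (1.502% and 1.75% against 2.33%). Since the lists of the female line Kc held them too, peaks on Y cannot be taken as signal from a Y chromosome, and their source was not tested. The mitochondrial genome held 7 to 13 peaks in each list.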
